A study of Mus musculus with 10 samples.

How the data were processed

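Single-cell mRNA and hashtag counts were analysed for mouse LysoDCs and cDC2s sorted from Peyer's patches and for blood cells with high CD115. Per the file headers, the deposited matrices hold raw UMI counts per gene or hashtag and cell barcode, written by Cell Ranger 6.0.1, whereas the notes of the authors name Cell Ranger 2.0.0 and the mm10 genome. No normalization had been applied to the counts before they were deposited. Each matrix had 32285 genes, and gene identifiers were matched to GRCm38 annotation for 99.6% of them (32158) and for all 24 genes whose positions were tabulated.

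Dataset 1 was a single library with 9 hashtags, each of which the labels assign to a sorted population. The 4 labelled libraries of dataset 2 share 1 matrix and 1 barcode suffix, and the LysoDC hashtags recur in all of them, so LysoDCs could not be traced to a library. By the labels, CD43+ monocytes came from 1 library, Ly6C+ monocytes from another and DN blood cells from the 2 others. Differences between blood populations of dataset 2 therefore include any between libraries, while dataset 1 had 1 library for all. The labels of dataset 2 do not assign its 4 LysoDC hashtags to LysoDC subsets, and its CCR2+ and CCR2- DN blood cells carried the same hashtag. For the dataset 2 library of mature LysoDCs, the hashtag list names immature cells while its title and cell type name mature cells, and the title was followed. The plan had called for 14 sums of cells over 7 populations. Because of the shared hashtags, 8 sums were used instead, made from total LysoDCs, Ly6C+ monocytes, CD43+ monocytes and DN blood cells in each dataset. LysoDC subsets and cDC2s were compared in dataset 1 only, and CCR2+ was not compared with CCR2-. Assigning LysoDCs of dataset 2 to subsets from their own expression was left out.

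Hashtags were called per dataset with HTODemux of Seurat 5.3.0 (positive quantile 0.99). Of 11878 and 13111 barcodes, 9069 and 8516 had 1 hashtag, 2038 and 4572 had several and were removed as doublets, and 771 and 23 had none. Cells needed at least 1000 UMIs, 500 genes and at most 10% mitochondrial UMIs, which 10178 and 10571 barcodes met. Both filters left 7878 and 7470 cells, with median depths per population between 2312 and 14346 UMIs. Totals per tested sum ran from 2483174 to 38177761 UMIs. Hashtag UMIs came to 10468097 and 13110596.

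Cells were clustered per dataset with scanpy 1.11.5 and the Leiden method of igraph 0.11.9 (2000 variable genes, 30 principal components, 20 neighbours, resolution 0.8), which gave 16 and 10 clusters. Clusters were named from 15 marker lists fixed beforehand. A cluster took a name when enough markers of a list were among its genes with the largest fold over all other cells of the dataset. Shares of cells have exact Clopper-Pearson 95% intervals. Cells are not replicates, so shares are set side by side per dataset without a test.

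Sums of raw counts per population and dataset were tested in edgeR 4.0.16 with TMM scaling, filterByExpr and robust quasi-likelihood fits, with dataset as a block. Each population thus had 2 pools of mice, and every p rests on these 2 pools and on a spread shared across populations (3 residual degrees of freedom, prior degrees of freedom 7.73, biological coefficient of variation 0.138). P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 11474 genes tested, with a threshold of 0.05. LysoDCs were set against the mean of the logarithms of both monocyte types, while the CPM printed for monocytes in that comparison are arithmetic means. On simulated data with known changes, 47.3% to 74.2% of 2-fold and 81.7% to 93.0% of 4-fold changes were recovered. There were 4 to 7 false calls among 11015 to 11054 genes. The simulated populations shared the same mean profile, with no effect of dataset or library and no spread specific to a gene. Only 85 to 115 genes were changed at each fold, whereas 1872 to 6654 genes passed in the measured comparisons. These figures therefore do not give the error rate of the reported calls.

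Altogether 34 lists with 561 genes were fixed beforehand, and 30 had enough tested genes. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. With the preset correlation 10 lists passed for LysoDCs against monocytes, 6 for CD43+ against Ly6C+ monocytes, 13 for DN blood cells against Ly6C+ monocytes and 8 against CD43+ monocytes. With an estimated correlation 0 passed in any of them.

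Genes were named by a rule fixed beforehand. For tested comparisons these were the 12 largest changes each way among genes past the threshold, with the same sign in both datasets and at least 50 CPM in the higher population of both, plus up to 4 members of a list by adjusted p. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and unnamed genes were not named, and genes of the sort gates served as gate checks only. Later tests of stray cells and of an Epcam-led cluster also used the gate genes Cd24a and Ccr2. From the genes so named, those with a call that held under the alternatives were preferred, so the printed genes are more stable than the named genes as a whole.

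For the 7 comparisons within dataset 1 there was 1 sum per population and no test. Ratios were formed from CPM + 5, and genes were named with at least 100 CPM in the higher population, a ratio of at least 3 and separate Poisson intervals, at most 10 each way, plus list members, which were picked among those with the larger ratios after their values were seen. List medians covered genes with at least 10 CPM, with intervals from 1000 Poisson draws. Their percentile was taken among 10000 random lists matched on expression, where 0 and 100 mean below or above every random list at the precision given. Genes of a random list were drawn independently, so the percentiles take no account of list members that move together. Small shifts of such lists can therefore reach extreme percentiles. The mean of the 3 other subsets served as the reference for follicular LysoDCs, and the interval around it spans those subsets. Correlations of DN blood cells with other populations were Spearman coefficients of log2 (CPM + 1) over genes with a mean of at least 50 CPM.

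Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors in place of TMM, no filter on low counts, no dataset block, sums thinned to equal totals, a hashtag call needing 80% of at least 10 hashtag UMIs, a stricter cell filter (2000 UMIs, 1000 genes, 5% mitochondrial UMIs), removal of cells with at least 2 UMIs of markers of other cell types, other clustering resolutions (0.4 and 1.5) and each sum left out in turn. A background-scaled hashtag call (top hashtag at least 1 log2 unit over its background and over the next) was added later, as were equal weights for the LysoDC subsets, fits without the Epcam-led cluster and, within dataset 1, limits of LysoDCs to clusters made mostly of LysoDC-tagged cells and of cDC2s to the others. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Lists, markers, tests, cell filters, naming rule and the first group of alternatives were fixed before the data were examined.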

Results

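Messenger RNA was counted in single mouse cells sorted from Peyer's patches and from blood. Peyer's patches are the lymphoid tissue of the small intestine, and their LysoDCs are lysozyme-expressing phagocytes of the region that samples gut antigens. Conventional type 2 dendritic cells (cDC2s) of the same patches and blood cells with high CD115 served as the populations beside them. The blood cells were Ly6C+ monocytes, CD43+ monocytes and cells negative for both markers (DN blood cells), which the study treated as candidate precursors. Blood came from mice given clodronate liposomes, which deplete phagocytes, 9 days earlier, whereas Peyer's patch donors were untreated. Every animal was a female C57BL/6Rj mouse. Sorted populations carried hashtags, antibodies bearing DNA barcodes that mark a cell's population of origin, and were then pooled.

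Dataset 1 was 1 library of 9 hashtagged populations from 30 Peyer's patch donors and 20 blood donors. Dataset 2 comprised 4 libraries and 7 hashtags from 20 Peyer's patch donors and 18 blood donors, and its cells were tagged before the sort instead of after it. In dataset 2 the 4 LysoDC hashtags could not be assigned to LysoDC subsets, and the CCR2+ and CCR2- gates of DN blood cells shared a hashtag. By the labels each blood population of dataset 2 was in libraries of its own, so its blood comparisons are also comparisons between libraries, whereas all populations of dataset 1 shared 1 library. Total LysoDCs, Ly6C+ monocytes, CD43+ monocytes and DN blood cells were therefore the 4 populations measured in both datasets. Their comparisons were tested with n = 2 pools of mice per population. Errors are approximate standard errors (SE): the size of the fitted change divided by the square root of its F statistic. For genes nearly absent from a population they are rough and should not be read as standard errors of the ratio. LysoDC subsets and cDC2s were measured separately in dataset 1 alone, with 1 sum of cells each and no replicate. For those comparisons no test was possible, and the intervals given are 95% Poisson intervals that cover counting error only.

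Dataset 1 held 91530239 gene UMIs (unique molecular identifiers, the counted molecules) in 11878 barcodes, and dataset 2 held 81034175 in 13111 barcodes. After hashtag calling and cell filters, 7878 and 7470 cells were used. In dataset 1 these were 644 follicular, 708 immature, 1065 intermediate and 469 mature LysoDCs, with 6673817, 9573905, 15564141 and 6365898 UMIs. The cDC2s comprised 1009 immature cells with 7706012 UMIs and 262 maturing cells with 2043004 UMIs. Blood gave 919 Ly6C+ monocytes (4081931 UMIs), 684 CD43+ monocytes (2483174 UMIs) and 2118 DN blood cells (9647662 UMIs) in dataset 1. Dataset 2 gave 681 LysoDCs (7326567 UMIs), 866 Ly6C+ monocytes (5197974 UMIs), 952 CD43+ monocytes (2596548 UMIs) and 4971 DN blood cells (28778760 UMIs). Of the 4 LysoDC hashtags of dataset 2, 1 gave 4 of these 681 LysoDCs, against 719 cells under a background-scaled hashtag call. The labels state 51100 sorted cells for dataset 1, of which the 7878 used cells are 15.4%, with 11.4% for CD43+ monocytes at the low end and 19.5% for mature LysoDCs at the high end.

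Transcripts of the proteins used for sorting followed the gates. Ly6c2 reached 1306 CPM (counts per 1000000 UMIs) in Ly6C+ monocytes, 116 in DN blood cells and 7.65 in CD43+ monocytes of dataset 1, and 1059, 10.98 and 2.31 in dataset 2. Spn, which encodes CD43, was at 692 and 688 CPM in CD43+ monocytes, against 48.8 and 54.6 in Ly6C+ monocytes and 105 and 61.2 in DN blood cells. Across the LysoDC gates of dataset 1, F11r stood at 2.40 CPM in follicular, 9.61 in immature, 55.9 in intermediate and 79.2 in mature cells. Emb was lowest in follicular LysoDCs (16.9 CPM) and lay at 90.6, 118 and 128 CPM in the immature, intermediate and mature gates.

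Clusters of cells by expression were named from fixed marker lists, and shares are given with exact Clopper-Pearson 95% intervals. CD43-high monocyte-like clusters held 90.9% (88.5-93.0) of CD43+ monocytes in dataset 1 and 98.2% (97.2-99.0) in dataset 2. Ly6C-high monocyte-like clusters held 77.0% (74.2-79.7) and 80.8% (78.0-83.4) of Ly6C+ monocytes. LysoDC-like clusters held 97.8% (96.4-98.8) of the LysoDCs of dataset 2, while no cluster of dataset 1 met that name. DN blood cells were mostly cDC2-like in dataset 1, at 75.6% (73.7-77.4), but 15.1% (14.1-16.1) met that name in dataset 2, where 78.7% lay in clusters that no marker list named. The name stands for fixed markers such as Cd209a rather than for likeness to the sorted cDC2s, of which 4 of 1009 immature (0.396%) and 7 of 262 maturing cells (2.67%) were in cDC2-like clusters. Of the immature cDC2s 888 lay in an unnamed cluster with 14.8 CPM of Cd209a, against 681 and 521.6 CPM in the cDC2-like clusters of dataset 1. Both DN shares depended on how finely cells were clustered, with 43.8% in dataset 1 at resolution 1.5 and 58.3% in dataset 2 at resolution 0.4. Names rest on genes with the largest fold over all other cells of the same dataset. DN blood cells were 2118 of 7878 cells in dataset 1 and 4971 of 7470 in dataset 2. Markers shared among DN clusters could thus lead less easily in dataset 2, so the DN shares of the datasets are not comparable.

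**Figure D1:**
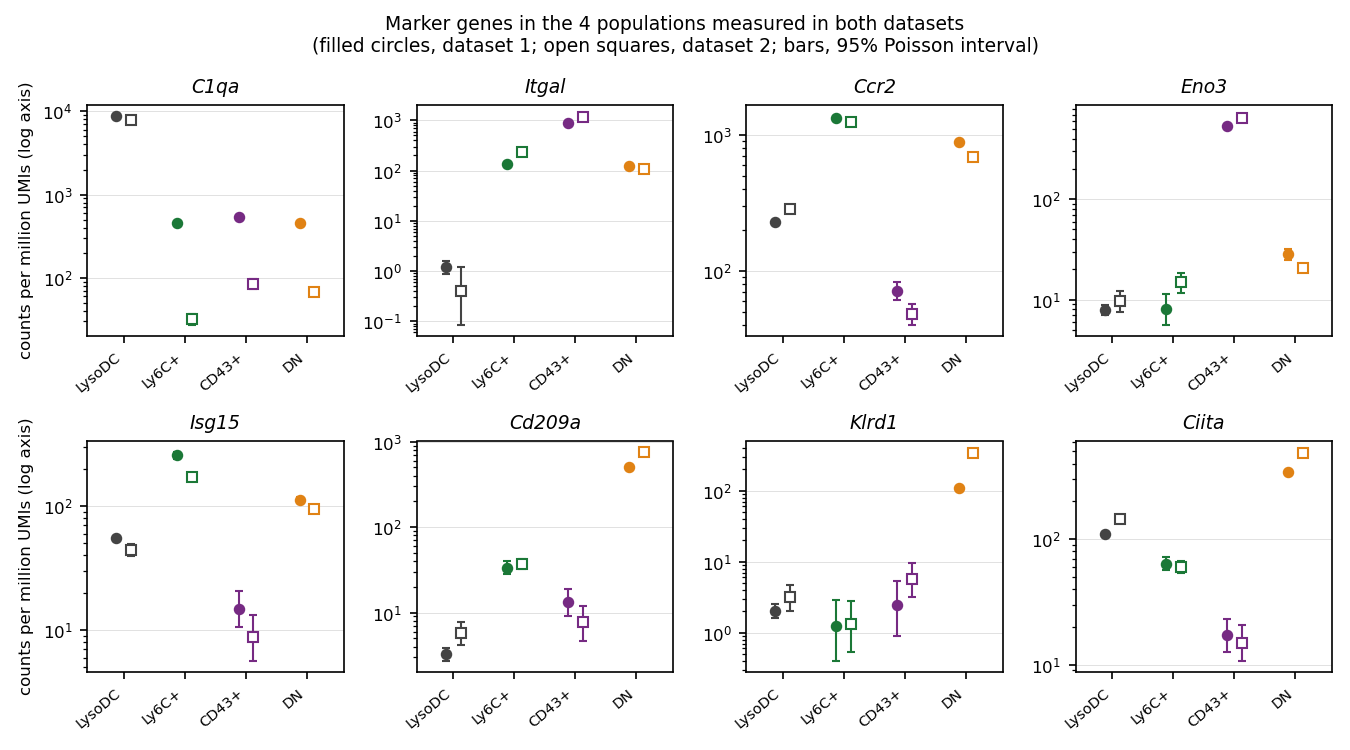
Counts per 1000000 UMIs (CPM, log axis) of 8 genes in LysoDCs, Ly6C+ monocytes, CD43+ monocytes and DN blood cells, as filled circles for dataset 1 and open squares for dataset 2, with bars for 95% Poisson intervals. C1qa was at 8787 and 7806 CPM in LysoDCs, Eno3 at 538 and 646 CPM in CD43+ monocytes, and Cd209a at 511 and 747 CPM in DN blood cells.

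LysoDCs were set against blood monocytes to ask what distinguishes the tissue cells from circulating cells of the monocyte lineage. Transcripts of the complement starter protein C1q and of the protease Adamdec1 were among the genes with the largest excess in LysoDCs. C1qa (ENSMUSG00000036887, GRCm38 chromosome 4, 136895917 to 136898803, minus strand) was 6.12 ± 0.85 log2 units higher (adjusted p = 0.0062), at 8787 against 492 CPM in dataset 1 and 7806 against 57.9 CPM in dataset 2. The dataset 1 blood level of C1qa was alike in Ly6C+ monocytes, CD43+ monocytes and DN blood cells, at 452, 532 and 454 CPM. The ratio within dataset 1 is therefore read as a lower bound. The fitted 6.12 joins datasets with unlike blood levels and is not a lower bound. Adamdec1 was higher by 5.77 ± 0.46 log2 units (adjusted p = 0.000583), and Spon1, for a matrix protein, by 5.59 ± 0.32 (adjusted p = 3.67e-06). In the other direction, the integrin chain gene Itgal (ENSMUSG00000030830, chromosome 7, 127296260 to 127335138, plus strand) was at -8.44 ± 0.47 (adjusted p = 1.58e-05), with 1.18 against 505 CPM and 0.409 against 711 CPM. The endocytic receptor gene Lrp1 was at -8.27 ± 0.25 (adjusted p = 7.17e-09), and Nr4a1, a transcription factor of CD43-high monocytes, at -7.56 ± 0.63. In all, 3467 genes were higher in LysoDCs and 3187 lower.

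Antigen presentation through MHC class II was higher almost as a whole, with 12 of 13 genes up and 1 not passing (camera adjusted p = 5.04e-05; 12 up adjusted over the list alone). The class II transactivator gene Ciita gained 2.18 ± 0.15 log2 units, the loading protein gene H2-DMa 2.15 ± 0.16 and the lysosomal reductase gene Ifi30 2.26 ± 0.16. Dendritic cell maturation and migration genes were 19 up, 6 down and 4 not passing (adjusted p = 0.0159; 20 up and 7 down adjusted over the list alone), with Relb up by 2.27 ± 0.12 and Nfkb1 at -2.08 ± 0.13. Lysosome genes were 21 up, 4 down and 8 not passing (adjusted p = 0.0124; the same counts adjusted over the list alone), among them the proteases Ctsz (2.75 ± 0.13), Tpp1 (2.14 ± 0.11) and Ctsc (2.14 ± 0.15). Each of these 3 lists had an adjusted p = 0.725 with an estimated correlation.

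Cell cycle genes stood out in number, with 25 of 28 higher in LysoDCs, 1 lower and 2 not passing (adjusted p = 7.18e-07; 25 up adjusted over the list alone; adjusted p = 0.725 with an estimated correlation). The spindle gene Tpx2 was higher by 5.88 ± 0.38 and Ube2c, whose product acts at mitotic exit, by 3.49 ± 0.24 log2 units. Among metabolic lists, those of cholesterol biosynthesis, glycolysis and oxidative phosphorylation moved the same way. Cholesterol biosynthesis had 18 of 22 genes up and 1 down (adjusted p = 7.54e-05; 0.791 with an estimated correlation), led by Dhcr7 at 3.95 ± 0.15. Glycolysis had 13 of 17 up and 2 down (adjusted p = 0.00714; 0.725 with an estimated correlation), with Hk2 up by 1.68 ± 0.12 and Pfkp at -2.13 ± 0.17. Oxidative phosphorylation had 18 of 31 up and 1 down (adjusted p = 0.00697; 0.921 with an estimated correlation), with Cox5a up by 1.68 ± 0.12. Adjusted over the list alone, the counts of these 3 lists were unaltered. Other metabolic lists went both ways, with lipid handling and LXR target genes 6 up and 10 down of 21 (adjusted p = 0.437; 7 up and 10 down adjusted over the list alone) and iron and heme genes 4 up and 5 down of 13 (adjusted p = 0.842; 4 up and 5 down adjusted over the list alone).

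Genes that define the blood monocytes were lower in LysoDCs. Of 23 CD43-high monocyte genes 17 fell and 2 rose (adjusted p = 6.81e-06; 18 down adjusted over the list alone), including Clec4a3 at -6.59 ± 0.19 and Pou2f2 at -5.35 ± 0.20. Ly6C-high monocyte genes were 12 down, 1 up and 7 not passing of 20 (adjusted p = 0.000807; 12 down adjusted over the list alone), with Ms4a4c at -5.18 ± 0.22 and the calcium-binding protein gene S100a4 at -3.92 ± 0.17. Both lists had an adjusted p = 0.725 with an estimated correlation.

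Phagocyte lists split within themselves. Phagocytic receptor genes were 7 up and 11 down of 22 (adjusted p = 0.277), with Axl up by 2.62 ± 0.21 and the Fc receptor genes Fcgr4 and Fcer1g at -6.17 ± 0.26 and -1.60 ± 0.14. Complement genes were 6 up and 3 down of 11 (adjusted p = 0.437), with the activator genes Cfb (4.51 ± 0.48) and Cfp (3.70 ± 0.14) up. Macrophage core genes were 10 up and 6 down of 21 (adjusted p = 0.415), with the Fc receptor gene Fcgr1 at -6.60 ± 0.45. Conventional DC core genes were 12 up and 7 down of 25 (adjusted p = 0.849), with Runx3 up by 3.26 ± 0.18 and Bcl11a at -3.99 ± 0.25. Adjusted over the list alone, the counts were 7 and 12 for phagocytic receptors, 6 and 3 for complement, 11 and 6 for macrophage core and 12 and 7 for the DC core. Interferon-stimulated genes were divided evenly, with 10 up and 10 down of 28 (adjusted p = 0.877; 10 and 10 adjusted over the list alone), the chemokine gene Cxcl9 being up by 4.62 ± 0.33 and Oas3 at -2.47 ± 0.24. Adhesion and trafficking genes were 8 up and 12 down of 23 (adjusted p = 0.523; 10 up and 12 down adjusted over the list alone), with Icam1 up by 1.79 ± 0.13 and the integrin gene Itga4 at -4.87 ± 0.19.

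Markers of other cells moved beside these groups, since all 4 platelet genes were up (adjusted p = 0.0212; 4 up adjusted over the list alone; 0.725 with an estimated correlation), Itga2b by 4.71 ± 0.42, as were 3 of 6 plasmacytoid DC genes (adjusted p = 0.277; 3 up adjusted over the list alone), including Ccr9 by 5.19 ± 0.45. Tissue, enzymatic digestion, CD11c enrichment and the clodronate treatment of blood donors all differed along with this comparison, so their shares in it cannot be separated.

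CD43+ monocytes were compared with Ly6C+ monocytes as the 2 known circulating monocyte types. Fabp4, encoding a fatty acid carrier, was 6.97 ± 0.36 log2 units higher in CD43+ monocytes (adjusted p = 1.33e-05), at 328 against 1.47 CPM in dataset 1 and 331 against 2.89 CPM in dataset 2. The enolase gene Eno3 (ENSMUSG00000060600, chromosome 11, 70657202 to 70662513, plus strand) was higher by 5.46 ± 0.27 (adjusted p = 3.87e-06) and the phosphatase gene Dusp16 by 6.04 ± 0.22 (adjusted p = 3.31e-07). Cd300e, for an activating receptor, was at 305.7 and 361 CPM against 0.490 and 0.192 CPM in Ly6C+ monocytes. The antiviral modifier gene Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818, minus strand) was at -4.38 ± 0.18 (adjusted p = 3.56e-07), with 14.9 against 258 CPM and 8.86 against 172 CPM. In all, 1652 genes were higher in CD43+ monocytes and 1761 lower. Without replicate 2 of Ly6C+ or of CD43+ monocytes the total of 3413 became 1561 and 1433, and without replicate 1 of CD43+ monocytes it became 2275.

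Interferon-stimulated genes were the most uniform group, with 26 of 28 lower in CD43+ monocytes, 2 not passing and 0 higher (adjusted p = 4.84e-15; 27 down adjusted over the list alone). Oasl2 was at -3.75 ± 0.20, Ifit1 at -4.47 ± 0.29 and Ifit3, whose counts are uncertain because of a near-identical copy, at -4.70 ± 0.28. The monocyte lists separated by gate. CD43-high genes were 18 up and 0 down of 23 (adjusted p = 6e-10; 18 up adjusted over the list alone), with Pparg up by 3.57 ± 0.29 and Bcl2a1b, also with near-identical copies, by 3.85 ± 0.17. Ly6C-high genes were 14 down and 0 up of 20 (adjusted p = 1.21e-08; 15 down adjusted over the list alone), with Ms4a4c at -4.01 ± 0.21, S100a6 at -2.18 ± 0.16 and S100a4 at -1.79 ± 0.16. Lipid handling and LXR target genes were 11 up, 3 down and 7 not passing of 21 (adjusted p = 0.031; 12 up and 3 down adjusted over the list alone), with the phospholipid carrier gene Pltp up by 2.14 ± 0.13 and Npc2 at -2.24 ± 0.15. For these 4 lists the adjusted p = 0.708 with an estimated correlation.

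Oxidative phosphorylation genes were 20 down and 0 up of 31 (adjusted p = 1.26e-06; 27 down adjusted over the list alone; 0.787 with an estimated correlation), with the ATP synthase gene Atp5g1 at -1.04 ± 0.17. MHC class II presentation was 4 down and 9 not passing of 13 (adjusted p = 0.0554; 5 down adjusted over the list alone), with H2-DMa at -2.41 ± 0.20, Ifi30 at -2.37 ± 0.21 and Ciita at -2.15 ± 0.22. Among markers of other cells, B cell genes were 5 up and 1 down of 12 in CD43+ monocytes (adjusted p = 0.0036; 6 up adjusted over the list alone; 0.708 with an estimated correlation).

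**Figure D2:**
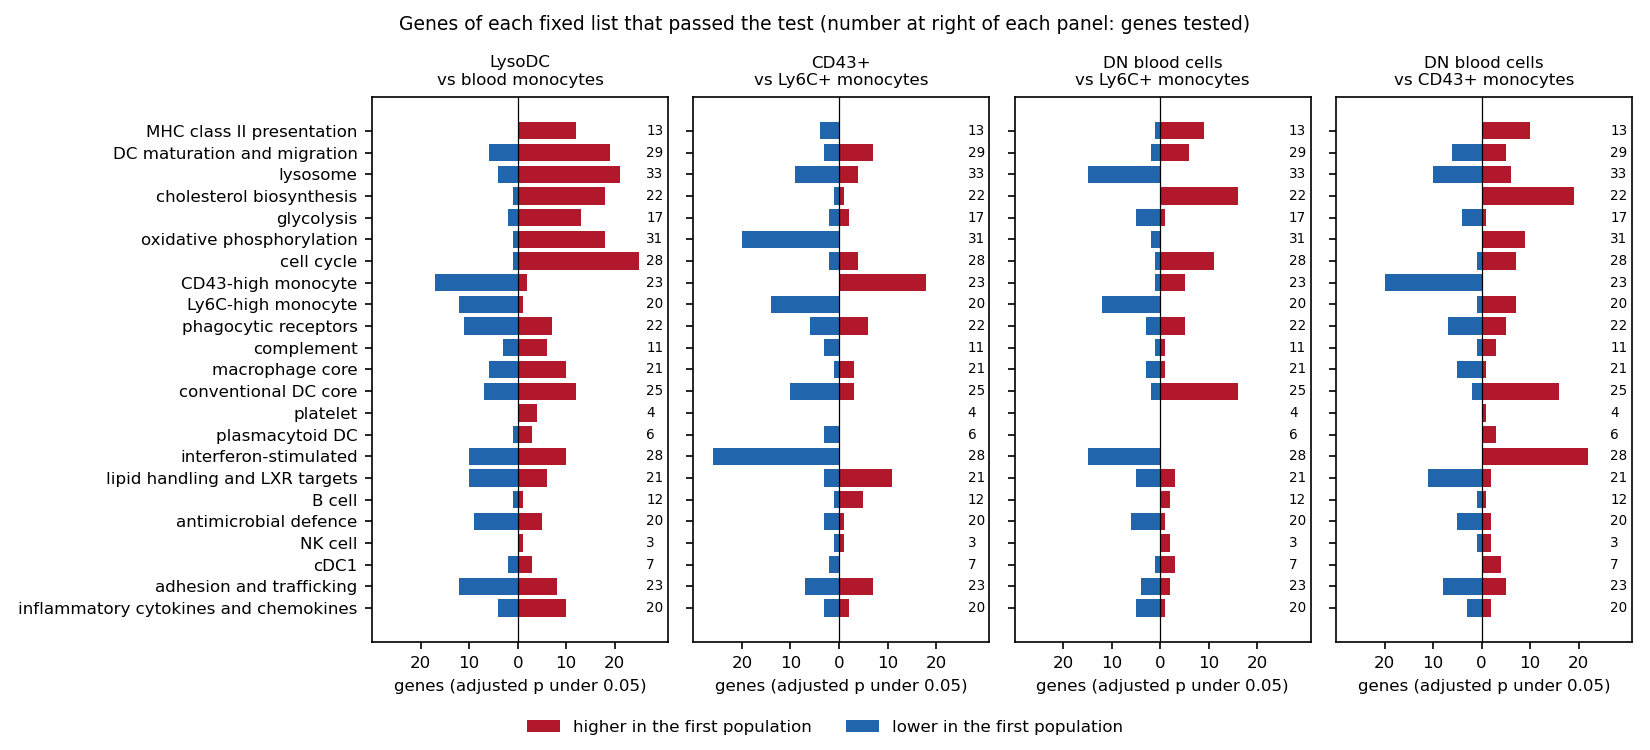
Numbers of genes (adjusted p under 0.05) higher, in red to the right, or lower, in blue to the left, in the first population of each of the 4 tested comparisons, for 23 fixed lists, with the number of genes tested at the right of each panel. Of 28 interferon-stimulated genes 26 were lower in CD43+ than in Ly6C+ monocytes, and of 22 cholesterol biosynthesis genes 16 and 19 were higher in DN blood cells than in Ly6C+ and in CD43+ monocytes.

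DN blood cells were compared with each monocyte type to ask what sets the candidate precursors apart. Against Ly6C+ monocytes, Klrd1 (ENSMUSG00000030165, chromosome 6, 129591782 to 129598775, plus strand), for a lectin-like receptor best known on killer cells, was 7.42 ± 0.37 log2 units higher in DN blood cells (adjusted p = 2.82e-05), at 107 against 1.22 CPM and 344 against 1.35 CPM. The C-type lectin gene Cd209a (ENSMUSG00000031494, chromosome 8, 3743397 to 3748984, minus strand) was higher by 4.16 ± 0.25 (adjusted p = 5.12e-05), at 511 against 33.6 CPM and 747 against 36.9 CPM. The related lectin gene Clec10a was higher by 3.29 ± 0.20 (adjusted p = 1.64e-05) and Cd7 by 5.35 ± 0.25. The kinase gene Rbks was at -2.75 ± 0.25. In all, 924 genes were higher in DN blood cells and 948 lower. The total of 1872 was sensitive to the replicates: it became 383 without replicate 2 and 1173 without replicate 1 of Ly6C+ monocytes, 917 without replicate 2 of DN blood cells, and 1082 without the dataset term.

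MHC class II presentation was higher in DN blood cells, with 9 of 13 genes up, 1 down and 3 not passing (adjusted p = 1.22e-06; 11 up and 1 down adjusted over the list alone). Ciita (ENSMUSG00000022504, chromosome 16, 10480059 to 10528418, plus strand) gained 2.74 ± 0.18 log2 units, at 340.1 against 63.9 CPM and 487 against 60.2 CPM, and H2-DMa gained 1.33 ± 0.19. Conventional DC core genes were 16 up and 2 down of 25 (adjusted p = 2.42e-07; 18 up and 2 down adjusted over the list alone), with Kmo up by 3.05 ± 0.21 and the Notch effector gene Rbpj by 1.30 ± 0.14. Cholesterol biosynthesis was up in 16 of 22 genes and down in 0 (adjusted p = 3.84e-08; 19 up adjusted over the list alone), with Cyp51 higher by 1.74 ± 0.21 and the pathway regulator gene Srebf2 by 1.16 ± 0.16. Cell cycle genes were 11 up, 1 down and 16 not passing of 28 (adjusted p = 0.000119; 12 up adjusted over the list alone), although Hmgb2 was at -0.96 ± 0.15. These 4 lists had an adjusted p = 0.464 with an estimated correlation.

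Several groups were lower in DN blood cells than in Ly6C+ monocytes. Ly6C-high monocyte genes were 12 down and 0 up of 20 (adjusted p = 1.52e-11; 18 down adjusted over the list alone). Interferon-stimulated genes were 15 down, 0 up and 13 not passing of 28 (adjusted p = 3.84e-08; 19 down adjusted over the list alone), with Ifit1 at -1.28 ± 0.17, Zbp1 at -1.11 ± 0.14 and Isg15 at -1.01 ± 0.14. Lysosome genes were 15 down and 0 up of 33 (adjusted p = 9.55e-06; 17 down and 1 up adjusted over the list alone), with Lamp2 at -1.03 ± 0.16 and the progranulin gene Grn at -0.88 ± 0.14. Antimicrobial defence genes were 6 down and 1 up of 20 (adjusted p = 2.54e-06; 13 down adjusted over the list alone), with the oxidase subunit gene Ncf4 at -1.27 ± 0.16. Inflammatory cytokine and chemokine genes were 5 down, 1 up and 14 not passing of 20 (adjusted p = 0.0299; 5 down and 1 up adjusted over the list alone), with the co-stimulatory ligand gene Tnfsf9 up by 2.22 ± 0.30. Among genes known as markers of other cells, 2 of 12 B cell genes (adjusted p = 0.00315) and 2 of 3 NK cell genes (adjusted p = 0.0458) were up, among them Klrk1 by 3.13 ± 0.35, each with 2 up adjusted over the list alone. Of 7 cDC1 genes 3 were up and 1 down (adjusted p = 0.636; 3 up and 2 down adjusted over the list alone), with Clec9a higher by 4.08 ± 0.35 and Batf3 by 0.94 ± 0.16. The lists given here that passed had an adjusted p = 0.464 with an estimated correlation.

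Against CD43+ monocytes, DN blood cells again had more Clec10a and Cd209a and higher class II presentation genes, and lower CD43-high monocyte genes. Clec10a was 6.71 ± 0.27 log2 units higher (adjusted p = 5.12e-07), at 436 against 6.44 CPM and 597 against 5.01 CPM. Cd209a was higher by 6.11 ± 0.30, the adhesion receptor gene Slamf7 by 5.26 ± 0.25 and Flt3, for a growth factor receptor of dendritic cells, by 5.77 ± 0.41. Dusp16 was at -4.19 ± 0.18 (adjusted p = 5.12e-07), with 17.3 against 302.4 CPM and 17.0 against 435 CPM, and Eno3 was at -4.37 ± 0.24. In all, 2051 genes were higher in DN blood cells and 1929 lower. The total of 3980 became 1777 without replicate 2 of CD43+ monocytes and 2594 without replicate 2 of DN blood cells.

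Of 13 MHC class II presentation genes 10 were higher in DN blood cells than in CD43+ monocytes and 0 lower (adjusted p = 8.12e-06; 11 up adjusted over the list alone), with Ciita up by 4.89 ± 0.22 and H2-DMb1 by 4.43 ± 0.34. Conventional DC core genes were 16 up and 2 down of 25 (adjusted p = 3.98e-05; 18 up and 3 down adjusted over the list alone), with Kmo up by 5.14 ± 0.29. Interferon-stimulated genes were 22 up and 0 down of 28 (adjusted p = 6.84e-09; 23 up adjusted over the list alone), with Isg15 higher by 3.37 ± 0.18 and Oasl2 by 3.01 ± 0.20. Of 23 CD43-high monocyte genes 20 were lower and 0 higher (adjusted p = 1.12e-11; 22 down adjusted over the list alone), with Pparg at -3.26 ± 0.25. Lipid handling and LXR target genes were 11 down and 2 up of 21 (adjusted p = 0.000506; 13 down and 2 up adjusted over the list alone), with the sterol exporter gene Abcg1 at -1.36 ± 0.15 and Npc2 up by 1.40 ± 0.14. These 5 lists had an adjusted p = 0.662 with an estimated correlation.

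Cholesterol biosynthesis was up in 19 of 22 genes in DN blood cells (adjusted p = 1.46e-06; 21 up adjusted over the list alone), with Mvd higher by 1.48 ± 0.21. Oxidative phosphorylation was up in 9 of 31 genes (adjusted p = 0.00156; 9 up adjusted over the list alone), with Atp5g1 higher by 1.09 ± 0.17. Both had an adjusted p = 0.767 with an estimated correlation. Beside these groups, NK cell genes were 2 up and 1 down of 3 (adjusted p = 0.204; 2 up and 1 down adjusted over the list alone), with Klrd1 higher by 5.94 ± 0.34. Of 7 cDC1 genes 4 were up and 0 down (adjusted p = 0.0529; 4 up adjusted over the list alone), with Batf3 higher by 3.85 ± 0.21 and Naaa by 0.96 ± 0.17.

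Which population the DN blood cells lay closest to was described by Spearman correlation across genes, which are not independent replicates. DN blood cells were closest to Ly6C+ monocytes, with rho = 0.935 over 2763 genes in dataset 1 and rho = 0.827 over 2774 genes in dataset 2. CD43+ monocytes followed at rho = 0.818 and rho = 0.610, and LysoDCs at rho = 0.531 and rho = 0.567. In dataset 1, immature and maturing cDC2s of the Peyer's patch gave rho = 0.695 and rho = 0.696. Peyer's patch populations also differ from blood populations in tissue, handling and clodronate treatment of the donors. Likeness by origin can therefore not be read from their coefficients. The genes were chosen by the mean over all populations of a dataset, those of the Peyer's patch included. Klrd1, high in DN blood cells, was also at 127 CPM in immature and 80.8 CPM in maturing cDC2s, whereas Cd209a was at 10.5 and 35.2 CPM in them. Within DN blood cells of dataset 2, 1725 of 4971 cells (34.7%) formed a cluster led by Epcam, an adhesion gene, and 784 formed a cluster led by the cholesterol genes Idi1, Fdps and Cyp51.

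LysoDC subsets were compared within dataset 1 to follow the sorted stages from immature through intermediate to mature, without a replicate check. Plet1 (ENSMUSG00000032068, chromosome 9, 50494525 to 50505482, plus strand), encoding a surface protein of epithelia and dendritic cells, was 11.9 times higher in mature (148 CPM, 139-158) than in immature LysoDCs (7.83, 6.16-9.82), with 40.7 CPM in the intermediate gate. Ltb, for the cytokine lymphotoxin beta, was at 15.4, 30.9 and 117 CPM in the immature, intermediate and mature gates, and Cd9, a tetraspanin gene, at 25.4, 66.5 and 106 CPM. Cp, for the copper carrier ceruloplasmin, ran the opposite way, at 131, 73.8 and 33.5 CPM. Mature exceeded intermediate LysoDCs in Ltb (3.39 times) and Plet1 (3.34 times), and no gene passed the size criteria between intermediate and immature LysoDCs. In clusters made mostly of LysoDC-tagged cells, immature, intermediate and mature LysoDCs still had 7.84, 40.5 and 141 CPM of Plet1 and 15.4, 29.2 and 60.8 CPM of Ltb. Outside those clusters lay 11.3% of mature and 0.424% of immature LysoDCs.

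Adhesion and trafficking genes were higher in mature than in immature LysoDCs, with a median log2 ratio of 0.67 (0.53-0.76) over 17 genes. That was above 100% of random lists matched on expression, whose genes were drawn independently of each other. However, the median was 0.30 in clusters made mostly of LysoDC-tagged cells. Ccr9 was at 226 against 123 CPM in all cells and 225 against 123 CPM in those clusters. Conventional DC core genes (17 genes, median 0.22, 0.12-0.35, percentile 100) and maturation and migration genes (22 genes, median 0.10, 0.05-0.20, percentile 99.6) were slightly higher, Cd86 at 63.8 against 35.2 CPM. MHC class II presentation barely differed (13 genes, median 0.04, 0.03-0.10, percentile 79.4), with Ciita at 129 against 110.4 CPM. Lower in mature LysoDCs were cell cycle genes (19 genes, median -0.38, -0.49 to -0.26, percentile 0), interferon-stimulated genes (21 genes, -0.33, -0.41 to -0.24, percentile 0) and macrophage core genes (16 genes, -0.30, -0.32 to -0.25, percentile 0). Complement genes were lower too (7 genes, -0.29, -0.34 to -0.27, percentile 0.1), as were those of oxidative phosphorylation (31 genes, -0.16, -0.17 to -0.12, percentile 0.01). In those clusters the DC core median was 0.14, the cell cycle median was -0.59 and the macrophage core and complement medians were both -0.20. Vcam1 was at 71.5 against 124 CPM and Rsad2 at 14.3 against 37.1 CPM. Plasma cell and B cell genes were also higher in the mature gate, with medians of 2.58 (2.40-2.78) over 5 genes and 1.86 (1.74-1.9965) over 4, which became -0.34 and -0.28 in the same clusters. Mzb1, a plasma cell gene, was at 43.0 against 3.03 CPM, and 14 mature LysoDCs (2.99%) were plasma cell-like.

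Smaller shifts separated the adjoining stages. Intermediate LysoDCs exceeded immature ones in glycolysis (17 genes, median 0.17, 0.10-0.19, percentile 100), with Pkm at 868 against 715 CPM, and in adhesion and trafficking (15 genes, 0.11, 0.06-0.19, percentile 100). Their maturation and migration genes had a median of 0.07 with an interval reaching below 0 (-0.0045 to 0.12, 22 genes, percentile 99.9), which became 0.14 when cells with markers of other cell types were removed, a step that left 547 of 2886 LysoDCs. Cell cycle genes (20 genes, -0.14, -0.21 to -0.09) and macrophage core genes (16 genes, -0.11, -0.15 to -0.08, percentile 0.03) were lower, Cd81 at 189 against 292 CPM. Immediate early genes (18 genes, -0.13, percentile 0.01) and B cell genes (3 genes, -0.24, percentile 0.39) were also lower, and plasmacytoid DC genes were higher (3 genes, 0.18, percentile 98.8). Mature exceeded intermediate LysoDCs in adhesion and trafficking (17 genes, 0.24, 0.16-0.37, percentile 100) and in MHC class II presentation (13 genes, 0.20, 0.16-0.21, percentile 100). The latter median was 0.14 in clusters made mostly of LysoDC-tagged cells, where the peptide-editing gene H2-Oa was at 12.3 against 7.61 CPM, beside 34.9 against 8.22 CPM in all cells. Maturation and migration genes had a median of 0.07 with an interval reaching below 0 (-0.01 to 0.13, 21 genes, percentile 97.5), and macrophage core genes one of -0.18 (-0.19 to -0.08, 17 genes, percentile 0), which was -0.068 in those clusters. Immediate early genes (20 genes, 0.26, 0.21-0.37, percentile 100), plasma cell genes (5 genes, 3.21) and B cell genes (4 genes, 2.09) were also higher in mature than in intermediate LysoDCs, with medians of 0.15, 0.094 and 0.25 in those clusters.

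**Figure D3:**
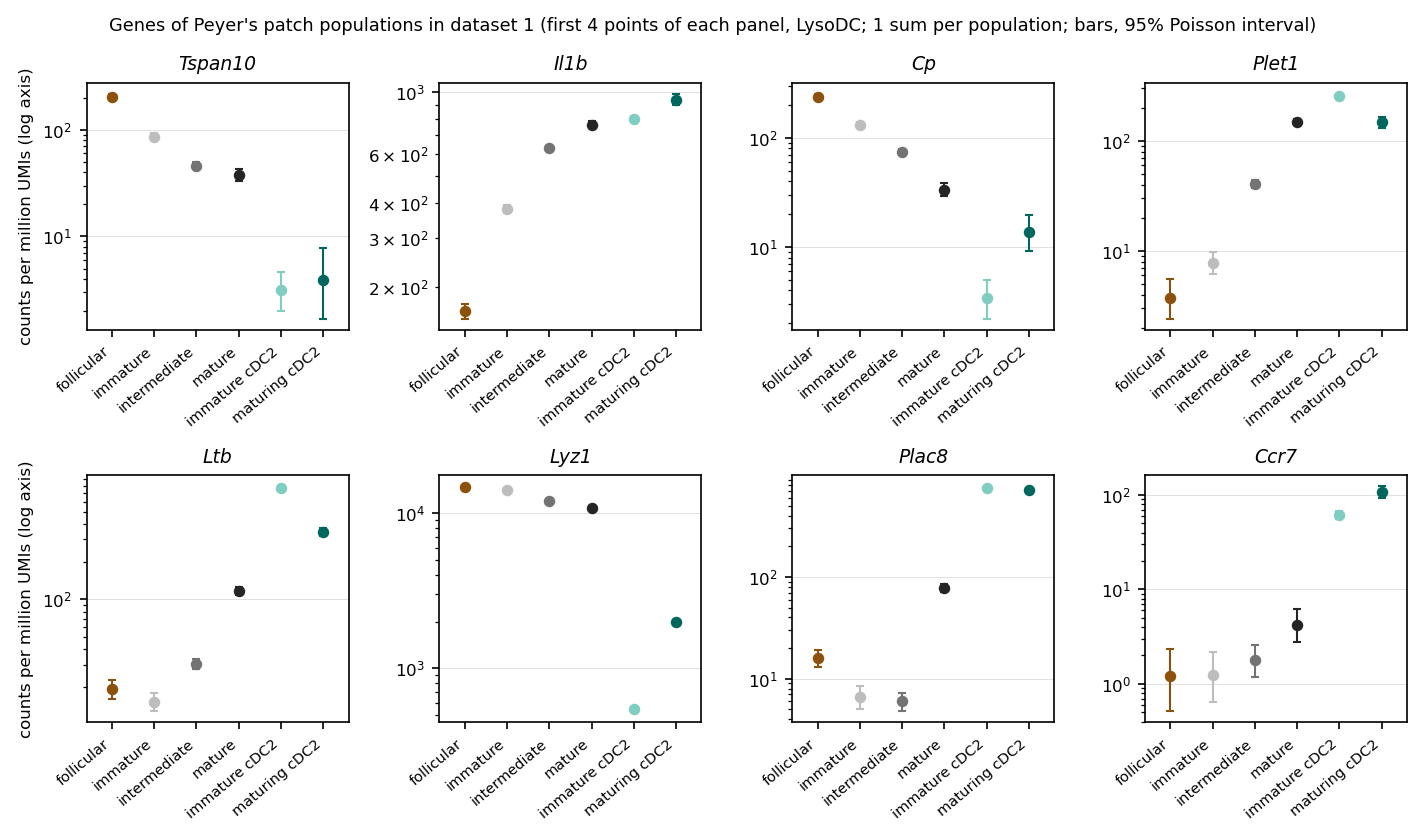
Counts per 1000000 UMIs (CPM, log axis) of 8 genes in the 4 LysoDC subsets and both cDC2 subsets of dataset 1, 1 sum of cells each, with bars for 95% Poisson intervals. Tspan10 fell from 205 CPM in follicular to 38.0 CPM in mature LysoDCs, Plet1 ran from 3.75 to 148 CPM, and Plac8 was at 754 and 709 CPM in immature and maturing cDC2s.

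Follicular LysoDCs were set against the mean of the other 3 subsets in dataset 1, again without a replicate check. The tetraspanin gene Tspan10 (ENSMUSG00000039691, chromosome 11, 120442644 to 120446950, plus strand) was 3.39 times higher, at 205 CPM (194-216) against 86.4, 45.9 and 38.0 CPM in immature, intermediate and mature cells. The inflammatory cytokine gene Il1b was 3.54 times lower, at 164 CPM against 379.8, 630.4 and 764 CPM, and the decoy receptor gene Il1r2 was 4.44 times lower. Clec4n, for a lectin that recognises fungi, was 3.35 times lower and S100a11 3.03 times lower. Of the 644 follicular LysoDCs 512 lay in a cluster led by Tspan10.

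Macrophage core genes were higher in follicular LysoDCs, with a median log2 ratio of 0.32 (0.31-0.35, 16 genes, percentile 100), which ranged from 0.25 under another hashtag call to 0.46 with other cell types removed. Ms4a7 was at 346 against 148 CPM, Selenop at 128 against 51.1 CPM and Vcam1 at 201 against 96.6 CPM. Complement (7 genes, 0.31, 0.30-0.32, percentile 99.9), interferon-stimulated (20 genes, 0.30, 0.24-0.40, percentile 100) and lysosome genes (29 genes, 0.14, 0.11-0.17, percentile 100) were higher as well, with C3 at 29.8 against 14.9 CPM and Irf7 at 79.1 against 44.7 CPM. Glycolysis was lower (17 genes, -0.71, -0.76 to -0.64, percentile 0), with the lactate exporter gene Slc16a3 at 45.4 against 106 CPM and Ldha at 269.9 against 476 CPM. Ly6C-high monocyte genes were lower (8 genes, -0.54, -0.62 to -0.46, percentile 0), S100a4 being at 44.7 against 111 CPM. B cell genes moved beside these groups (4 genes, 0.87, 0.78-0.97, percentile 100), with Cd79a at 43.8 against 22.7 CPM. In clusters made mostly of LysoDC-tagged cells, the medians of the Ly6C-high monocyte and B cell lists were -0.27 and 0.47, and follicular LysoDCs had 4.86 CPM of Cd79a. Medians of 5 plasma cell, 4 cDC1 and 4 plasmacytoid DC genes were -0.55, 0.28 and 0.26 in all cells and -0.28, 0.41 and 0.22 in those clusters.

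Immature cDC2s were set against immature LysoDCs in dataset 1 to contrast the 2 dendritic cell types of the patch at matched stages, without a replicate check. Plac8 was 65.6 times higher in cDC2s, at 754 CPM (735-774) against 6.58, and Epcam, Id2, for a transcription factor of dendritic cell development, and Ltb were 58.8, 55.0 and 38.1 times higher. Flt3 was at 106 against 0.627 CPM. LysoDCs had more of the secreted phospholipase gene Pla2g2d (29.2 times) and the itaconate synthase gene Acod1 (26.3 times). They also had at least 37.1 times more C1qc, 30.6 times more C1qb and 27.4 times more C1qa, given as lower bounds because C1qa in immature cDC2s (326 CPM) lay below its level in every blood population of dataset 1 (452 to 532 CPM). Lyz1, for the lysozyme that names the cells and with counts uncertain because of its near-identical neighbour, was at 547 against 14006 CPM.

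Complement genes had a median log2 ratio of -4.28 (-4.36 to -4.20, 6 genes) and macrophage core genes one of -3.64 (-3.80 to -3.52, 15 genes) in immature cDC2s against immature LysoDCs, both at percentile 0. Lysosome genes (28 genes, -1.10, -1.19 to -1.06, percentile 0) and interferon-stimulated genes (19 genes, -1.36, -1.57 to -1.27, percentile 0) were lower, with Ctsd at 87.1 against 1035 CPM and Zbp1 at 6.36 against 54.0 CPM. Conventional DC core genes were higher (22 genes, 1.86, 1.77-1.95, percentile 100), with a lowest median of 1.37 over the alternatives, and so were maturation and migration genes (28 genes, 0.65, 0.57-0.72, percentile 100), with Cd83 at 100.4 against 3.24 CPM. Immediate early genes, which tissue dissociation raises, were higher as well (24 genes, 1.74, 1.60-1.79, percentile 100), with Jun at 790.3 against 103 CPM. Among genes of other cells, plasma cell genes had a median of 2.26 (2.003-2.44, 5 genes), cDC1 genes one of 1.89 (1.74-2.02, 5 genes) and B cell genes one of 1.70 (1.57-1.84, 4 genes), and 13 immature cDC2s (1.29%) were plasma cell-like.

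At the later stage, maturing cDC2s were set against mature LysoDCs. Clusters made mostly of LysoDC-tagged cells held 17.2% of the maturing cDC2s, and 11.3% of the mature LysoDCs lay outside them. Values are therefore also given between mature LysoDCs inside those clusters and maturing cDC2s outside them. Ccr7, for the receptor that directs dendritic cells to T cell zones, was 12.2 times higher in cDC2s, at 108 CPM (93.9-123) against 4.24 (2.80-6.17), and at 131 against 1.02 CPM between the restricted cells. Ccr7 was 99.6 times higher in a mature DC-like cluster than in the rest of dataset 1, and that cluster held 42 of the 262 maturing (16.03%) and 72 of the 1009 immature cDC2s (7.14%). Plac8 was at 709 against 77.1 CPM in all cells and 867 against 9.56 CPM in the restricted ones, Id2 at 492 against 52.8 and 599 against 9.90 CPM, and Cd83 at 154 against 11.9 and 189 against 4.78 CPM. LysoDCs had more of the protease gene Ctsd, with 940.3 against 112 CPM in all and 1014 against 55.7 CPM in restricted cells, and more of the lipid carrier gene Apoe, with 12558 against 2130 and 13475 against 627 CPM. Higher in all cells and in restricted cells were the medians of 25 conventional DC core genes (1.41, 1.24-1.53, and 1.84), 28 maturation and migration genes (0.81, 0.65-0.89, and 0.96) and 20 cell cycle genes (1.10, 0.82-1.20, and 1.54). So were those of 22 immediate early genes, which tissue dissociation raises (1.249, 1.06-1.32, and 1.63), and of 5 cDC1 genes (1.99 and 2.81). Lower in both were those of 6 complement genes (-2.09 and -4.23), 15 macrophage core genes (-2.08 and -3.50) and 31 lysosome genes (-0.98, -1.10 to -0.91, and -1.22). The plasma cell median of -1.68 and the B cell median of -0.85, over 5 genes each, turned to 0.30 and 1.29 between the restricted cells.

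Maturing and immature cDC2s of dataset 1 were compared last, also without a replicate check. The chemokine gene Ccl5 was 7.89 times higher in maturing cells, at 129 against 11.9 CPM, and Ccr7 was at 108 against 61.6 CPM, Ccl17 at 67.5 against 27.8 CPM and Il12b at 34.8 against 8.95 CPM. Maturation and migration genes had a median log2 ratio of 0.29 (0.19-0.36, 30 genes, percentile 100), which was 0.14 under the background-scaled hashtag call. Cell cycle genes had one of 0.23 (0.16-0.32, 22 genes), whereas conventional DC core genes were lower (24 genes, -0.28, -0.35 to -0.20, percentile 0). Immediate early genes, which tissue dissociation raises, were lower too (26 genes, -0.26, and -0.14 outside clusters made mostly of LysoDC-tagged cells). LysoDC genes were higher in the maturing gate too, with C1qc, C1qb and C1qa at least 6.91, 5.68 and 4.99 times higher. These are lower bounds because of the C1qa level of immature cDC2s, as above. The medians were 2.32 (2.25-2.40) over 5 complement and 1.20 (0.96-1.35) over 14 macrophage core genes. Clusters made mostly of LysoDC-tagged cells held 17.2% of maturing and 2.08% of immature cDC2s. Without those cells C1qa was at 284 against 299 CPM and the medians were -0.060 and -0.067, while Ccr7 was at 131 against 62.2 CPM and the medians of maturation, cell cycle and DC core genes were 0.33, 0.41 and -0.16. Interferon-stimulated genes were higher (13 genes, 0.60, 0.35-0.70), with Irf7 at 18.6 against 7.14 CPM, and B cell (-0.35, -0.56 to -0.18, 4 genes) and plasma cell genes (-1.69, -2.04 to -1.35, 5 genes) were lower.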

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

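Of the tests in this part, the bound applied to free RNA was chosen after the result was seen, and the background-scaled hashtag call and all restrictions to certain clusters were added after the data had been seen.

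Barcodes called as carrying several hashtags enter no comparison. In dataset 2, 89.4% of them (4089 of 4572) had at least 80% of their hashtag UMIs from 1 hashtag, against 28.8% (587 of 2038) in dataset 1. A dominant hashtag is no sign of a single cell by itself, because hashtag levels differed between populations. Median counts of the own hashtag were 1437 UMIs in cells of 1 LysoDC hashtag and 170 UMIs in DN blood cells of dataset 2. Droplets with 2 cells are argued against for 6 hashtags. Over these, the median ratio of median gene UMI counts, barcodes with a dominant hashtag to barcodes with 1 hashtag, was 1.03 (0.961 to 1.14). A partner as shallow as a CD43+ monocyte (median 2312 UMIs) adds little to a LysoDC (8999 UMIs), so this ratio could miss such droplets. The hashtag that dominated most often, in 735 of the 2692 such barcodes past the cell filter, had too few cells with 1 hashtag for a ratio. Many of the barcodes with the other 6 hashtags may therefore be single cells. Of the 2692, 2165 were LysoDCs under the background-scaled call, with 7725 CPM of C1qa against 7806 CPM in the LysoDCs used. Their Cd209a was at 8.59 CPM, against 5.73 CPM in the LysoDCs used and 747 CPM in DN blood cells of dataset 2. Whether cutoffs placed within the background of the tags caused these calls stays open, because barcodes chosen for a dominant hashtag were almost bound to have 1 hashtag under the background-scaled call (97.3% did). No biological explanation was tested.

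The most mature gates of LysoDCs and cDC2s in dataset 1 shifted in opposite directions by a median of at least 0.25 log2 units each for 6 gene lists, when the median log2 ratios of mature to immature LysoDCs and of maturing to immature cDC2s were set side by side. Complement genes had -0.29 in LysoDCs and 2.32 in cDC2s, macrophage core genes -0.30 and 1.20, and interferon-stimulated genes -0.33 and 0.60. Plasma cell genes had 2.58 and -1.69, B cell genes 1.86 and -0.35, and plasmacytoid DC genes 0.47 and -0.66. For all but 1 of these 6 lists the opposition ended with LysoDCs limited to clusters made mostly of LysoDC-tagged cells and cDC2s to the other clusters: complement genes then had -0.20 and -0.060, macrophage core genes -0.20 and -0.067, plasma cell genes -0.34 and -1.49, B cell genes -0.28 and -0.13, and plasmacytoid DC genes -0.084 and -0.47. Interferon-stimulated genes kept it, at -0.30 over 21 genes and 0.63 over 13. The cells were limited by expression clusters, so the opposition was almost bound to end for lists that mark the removed cells. Its end therefore decides nothing about what those cells are. Each comparison applied its own floor of 10 CPM, so the medians set side by side do not cover the same genes of a list. Lists under that size in 1 of the comparisons were opposed as well, among them cell cycle genes (-0.38 and 0.23) and conventional DC core genes (0.22 and -0.28), which stayed opposed in the restricted cells at -0.59 and 0.41 and at 0.14 and -0.16. With 1 sum per population the difference between the LysoDC and the cDC2 ratios was not tested.

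The most mature gate of each subset in dataset 1 also carried more of the other subset's genes, and clusters of cells within the gates held these excesses to different degrees. In maturing cDC2s the excess lay in cells that clustered with LysoDC-tagged cells. The median over 16 complement and macrophage core genes went from 1.20 (0.95-1.34) to -0.0667 (-0.19 to 0.02) without them. They were 17.2% of maturing and 2.08% of immature cells, in 6 clusters made mostly of LysoDC-tagged cells. Stray LysoDCs in the gate need such a value. The cells were chosen by expression clusters, however, so their removal was almost bound to give it, and what these cells are stays open. Free LysoDC RNA in the droplets was tested by C1q and Lyz1 UMIs per cell. Outside those clusters they were 0.887 times as many in maturing as in immature cDC2s, beside 4.77 times over all cells. Both gates shared 1 library and cells of LysoDC clusters were left out, so a ratio near 1 was almost bound to follow. It decides nothing about free LysoDC RNA present alike in both gates. The bound written for this test beforehand read a ratio near 1 as a sign of free RNA. It was turned round after the result was seen, and no conclusion is drawn from either version. In mature LysoDCs, cDC2-like and other cells do not account for the whole excess of Plet1, Ltb, Cd9 and Ifitm1.

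Among cells of LysoDC clusters, the median log2 ratio of mature to immature LysoDCs was 1.76 (1.63-1.90) over Plet1, Ltb, Cd9 and Ifitm1, against 2.23 (2.09-2.36) in all cells. For Plac8, Epcam, Cd24a and H2-Oa it was 1.48 (1.30-1.67), against 2.72 (2.56-2.88). Plac8 itself came down to 9.56 against 6.27 CPM and H2-Oa to 12.3 against 5.96 CPM. Epcam was at 28.0 against 1.67 CPM and Cd24a at 42.7 against 3.87 CPM. Cd24a is a gene of the sort gates, so this median rests partly on the gate and decides nothing about cDC2-like cells. A biological change of LysoDCs on maturation is a candidate explanation for what remained, as a hypothesis drawn from the same data, while stray cells may explain most of the Plac8 and H2-Oa excess.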

How the results depend on the processing

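The background-scaled hashtag call, the equal weighting of LysoDC subsets, the removal of the Epcam-led cluster and the restrictions to or exclusion of LysoDC clusters were chosen after the data had been seen; the other alternatives were planned.

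Numbers of genes past the threshold stayed within 1.5 times the reported numbers in 34 of the 35 values from alternatives other than leaving out a replicate. For LysoDCs against monocytes they ran from 5113 with other cell types removed to 7093 without a filter on low counts. Without the replicate block, DN blood cells against Ly6C+ monocytes gave 1082 genes in place of 1872. The 80% hashtag call left fewer than 30 Ly6C+ monocytes, CD43+ monocytes and DN blood cells in dataset 1, so the tested comparisons could not be fitted with it, and it left too few maturing cDC2s for a value. DESeq2, the block and leaving out replicates have no counterpart where there is 1 sum per population, the depth comparison of CCR2+ with CCR2- cells was not run because they share a hashtag, and the added transfer of LysoDC subset labels to dataset 2 was not run because it would have set groups from the measured values.

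Leaving out 1 sum at a time mattered more, and the lone remaining sum is then assumed to vary like the other populations. The range was 4816 to 6942 for LysoDCs against monocytes, 1433 to 3747 for CD43+ against Ly6C+ monocytes, 383 to 2328 for DN blood cells against Ly6C+ monocytes and 1777 to 3986 against CD43+ monocytes. Each low end except that of LysoDCs left out a blood sum of dataset 2. S100a9, higher in DN blood cells than in Ly6C+ monocytes, ran from -2.15 without replicate 1 of Ly6C+ monocytes to 5.47 without their replicate 2. Over the 252 named genes of tested comparisons, 1842 values kept direction and call with a replicate left out and 170 lost the call with the direction kept, while 2153 kept both and 39 lost the call under the other alternatives. At least 1 of these alternatives removed the call of 34 of 64 named genes for DN blood cells against Ly6C+ monocytes, 16 of 47 for CD43+ against Ly6C+ monocytes, 9 of 51 for DN blood cells against CD43+ monocytes and 8 of 90 for LysoDCs against monocytes. Losses were most frequent without replicate 2 of Ly6C+ monocytes (34 genes), and the cause was not tested.

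Among comparisons within dataset 1, list medians outside their counting interval were frequent. Removing cells that bear markers of other cell types left 547 of 2886 LysoDCs of dataset 1, with 119 of 469 mature and 105 of 708 immature ones, so it is a change of most cells. With it the B cell median of mature against immature LysoDCs went from 1.86 to -0.17, the plasma cell median from 2.58 to 0.00, Cd79a and Mzb1 to 0.00, the maturation median of intermediate against immature LysoDCs to 0.14, the macrophage core median of follicular LysoDCs to 0.46 and the DC core median of immature cDC2s against immature LysoDCs to 1.76. The B cell median went to -0.13 for immature cDC2s against immature LysoDCs and to 0.00 for maturing cDC2s against mature LysoDCs. The zeros follow from the alternative's own construction, which removes cells by such markers. In cells of LysoDC clusters only, the B cell and plasma cell medians were -0.28 and -0.34 and Mzb1 was at -0.41, the macrophage core median of follicular LysoDCs was 0.31 and Cd83 in mature against intermediate LysoDCs was at -0.027. Between LysoDCs of those clusters and cDC2s outside them, the DC core median of maturing cDC2s against mature LysoDCs was 1.84 in place of 1.41 the plasma cell median 0.30 in place of -1.68 and the B cell median 1.29 in place of -0.85. The macrophage core median of follicular LysoDCs, 0.32 as reported, was 0.25 with the 80% hashtag call, 0.30 with the strict cell filter, 0.28 with the background-scaled call, 0.28 with size factors of DESeq2 and 0.31 without a filter on low counts. The DC core median of immature cDC2s, 1.86 as reported, was 1.37 with the 80% call, 1.63 with size factors of DESeq2 and 1.37 without a filter on low counts.

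For maturing against immature cDC2s the maturation median of 0.29 became 0.14 with the background-scaled call and 0.39 with size factors of DESeq2, and the B cell median became 0.019 without a filter on low counts. Without cells of LysoDC clusters the complement median was -0.060, the macrophage core median -0.067, Adamdec1 -0.14, C1qa -0.074, C1qb -0.060, C1qc -0.016 and Lyz1 -0.28. Except where a construction is named, the cause was not tested. In all, 266 list medians stayed within their interval, 169 lay outside it with the same sign and 11 turned, and of the values of 118 named genes 681 stayed, 213 moved and 9 turned.

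Shares of cells in named clusters moved with the resolution of clustering. At 0.4 they were 98.0% for CD43+ monocytes and 83.6% for Ly6C+ monocytes of dataset 1, and 96.9% for Ly6C+ monocytes and 58.3% for DN blood cells of dataset 2. At 1.5 they were 73.8% and 75.5% for Ly6C+ monocytes of datasets 1 and 2 and 43.8% for DN blood cells of dataset 1. With a floor of 10 CPM, correlations of DN blood cells were 0.693 and 0.680 with LysoDCs and 0.777 with CD43+ monocytes of dataset 2, and Ly6C+ monocytes remained the closest population. The other 18 shares and 15 correlations differed by less than their interval or the spread between datasets. With all sums thinned to 2483174 UMIs, 5313, 3210, 1482 and 3416 genes passed in the tested comparisons, among 10141 genes tested in place of 11474.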

Other observations

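All tests of the Epcam-led cluster in this part were chosen after the result was seen.

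Of the DN blood cells of dataset 2, 34.7% (1725 of 4971) formed a cluster led by Epcam (ENSMUSG00000045394, GRCm38 chromosome 17, 87635979 to 87651129, plus strand), with 61.8 CPM of Epcam against 0.679 CPM in the other DN blood cells. Epithelial cells are argued against, because the highest of Krt8, Krt18, Krt19, Fabp2 and Vil1 reached 0.726% of the Epcam level. The median UMI count of the cluster was 0.472 times that of the other DN blood cells (3481 against 7376 UMIs), where droplets with 2 cells would raise it. By the labels the CCR2+ and CCR2- gates were in different libraries, so the ratio may include a difference in depth between libraries. It therefore does not decide about droplets with 2 cells. When cells with at least 2000 UMIs were thinned to 2000, 28.1% of 1672 such cells of the cluster had a Ccr2 UMI against 68.0% of 3167 other DN blood cells, a share 41.3% as large. The share was 6.46% in those CD43+ monocytes that were deep enough, which leaves out shallower cells of a population with a median depth of 2312 UMIs. The cluster may therefore hold many cells of the CCR2- gate, which the shared hashtag leaves open, and the lower depth of its cells has no tested cause.

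Without that cluster the number of genes past the threshold was 1888 for DN blood cells against Ly6C+ monocytes and 4103 against CD43+ monocytes, beside 1872 and 3980 with it. In dataset 1, Epcam was at 3.32 CPM in DN blood cells, 387 CPM in immature cDC2s and 221 CPM in maturing cDC2s.

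A transcript abundant in LysoDCs was counted in blood barcodes at levels that differed between the datasets. Lyz1, with counts uncertain because of its near-identical neighbour, was at 786, 830.4 and 722 CPM in Ly6C+ monocytes, CD43+ monocytes and DN blood cells of dataset 1, and at 129, 191 and 117 CPM in dataset 2, against 12775 and 12059 CPM in LysoDCs. In dataset 1, 92.6% to 95.7% of cells had a Lyz1 UMI in each of the 6 clusters of blood cells, at 637 to 916 CPM, as RNA shared among droplets would give. No share of such RNA was estimated, so these values do not show that blood cells expressed it.

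Mature DC-like clusters held 42 of 262 maturing cDC2s and 72 of 1009 immature cDC2s of dataset 1. T cell-like clusters held 2 maturing (0.763%) and 6 immature cDC2s (0.595%). Of 1009 immature cDC2s 888 lay in a single cluster, which also held 164 of the 262 maturing cDC2s.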
